A study of Homo sapiens with 18 samples.

How the data were processed

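Total RNA from 18 samples of U2OS cells in 6 groups of 3 was hybridized to single-colour Illumina arrays after biotin labelling of 750 ng of RNA, per the labels' protocols. The groups were taken from the labels: an ERα or an ERβ vector, each without doxycycline, with doxycycline, and with doxycycline plus E2. No sample was left out.

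The authors deposited a non-normalized table with 1 probe intensity per array, which per the file headers had not been normalized between arrays. Its values were all above 100, with the lowest per array between 107 and 126, and the highest between 72091 and 74741, so no background had been subtracted to 0. The same table holds a deposited detection p-value for each probe and array, per the file headers. The authors also deposited processed intensity values, for which the submitters' processing notes name lumi. Their steps, background correction, scale and any centring are not stated in the sources used here. They were on a linear scale with column medians of 170.4 to 173.4. All columns labelled replicate 2 shared 1 distribution, with a median of 171.2, and kept the ranks of their raw signals (rank correlation 1), while those of replicates 1 and 3 did not (0.973 to 0.980). The sources used here do not say whether the authors adjusted the values by replicate. In deviations from the group means, same-numbered columns correlated at a median of -0.187, against 0.378 in the non-normalized table after normalization. This argues against values left unadjusted by replicate, but the way they were adjusted stays unknown. These values were used only as an alternative, with rows named through the probe identifiers.

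The columns of the non-normalized table are numbered 1 to 9 within each line. Columns 1 to 3 carry the name and number of their sample, and columns 4 to 6 (doxycycline) and 7 to 9 (doxycycline plus E2) are known only by their group. Arrays are named here by group and column number. For the fits that need replicate numbers, these columns took the number of the processed column of their group with the best rank match (0.973 to 1, against at most 0.944 with any other), a step chosen after the data had been seen. Arrays with the same number form a replicate set of 6.

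Of 48804 probe lines, 1 repeated line was dropped, which left 48803 probes. In the probe annotation 27578 of these had 1 gene symbol, 13 had several and 21212 had none. The entrez identifiers of 27541 were found in the reference gene table, which changed 0 symbols. Probes without exactly 1 symbol are not named. Signals were background-corrected by normexp with the detection p-values and quantile-normalized (neqc in limma, offset 16, log2). Probes with a detection p below 0.01 on at least 3 of 18 arrays were kept, 24226 in all, and each gene was represented by its kept probe with the highest mean, which gave 13505 genes. Among 4899 further kept probes of these genes, those called in a direction opposite to the chosen probe numbered 3, 2, 0 and 1 for E2 in the ERα line, E2 in the ERβ line, doxycycline in the ERα line and doxycycline in the ERβ line, 2 and 0 for the E2 and doxycycline differences and 62 for the lines without doxycycline. None belonged to a named gene. PGR had 1 probe and TFF1 had 1 probe, none detected on any array, so neither is reported. The detected range began at a normalized level of 6.08 to 6.53, depending on the array, and changes below it could not be seen. Arrays of a group correlated across genes at 0.984 to 0.994, and 0 pairs of arrays were identical.

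The 6 group means were fitted jointly to all 18 arrays with lmFit and tested with eBayes in limma (12 residual and 2.66 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. All tests were 2-sided. The comparisons were E2 within each line, doxycycline within each line, the difference of each response between lines (ERβ minus ERα), and ERβ against ERα without doxycycline. Named genes were chosen by a rule fixed before the data were examined, as were the comparisons, the lists and the alternatives not described as added. The rule took ESR1 and ESR2, GREB1, PGR, TFF1, KRT19 and CCN5, the 8 largest rises and 8 largest falls of each E2 and doxycycline comparison (6 for differences, 5 without doxycycline) among called genes whose groups of arrays did not overlap, which chance gives for 10% of genes, and up to 4 members of each list that passed or had at least 3 called members. Symbols of uncharacterized genes were passed over. Further examples of overlaps were the genes with the largest changes in both comparisons.

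The 21 gene lists covered classical estrogen targets, estrogen targets from earlier U2OS studies, proliferation, DNA replication and E2F targets, NF-kB and cytokines, interferon-stimulated genes, bone, ATF4 and amino-acid stress, the mitochondrial respiratory chain, TGF-beta and YAP, collagens and matrix, p53 targets, cholesterol and lipid synthesis, immediate-early genes, heat shock, nuclear receptor cofactors, ribosomal proteins, and markers of epithelial cells, fibroblasts, blood cells and endothelial cells. They were tested by camera in limma with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The outcome of fry is not reported here. A total of 14 genes are in several lists, and no list was chosen on these arrays. The overlap of comparisons that share arrays was set beside 20 simulated datasets of unchanged groups and beside the product of the call rates.

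The pairing by replicate number was checked on deviations from the group means. For the groups compared directly there were 15 pairs of same-numbered arrays, and the lowest correlation among them was 0.151, so the numbers were taken to pair the samples. Over all groups the median correlation was 0.378 for same-numbered arrays (lowest 0.061), against -0.197 for arrays with other numbers, and 16 of 18 arrays were closest to their own number. The numbers come from the labels for columns 1 to 3 and from the rank match for the rest. In the authors' values the median of same-numbered arrays was -0.187, against 0.086 for arrays with other numbers, so a replicate effect of this kind was not left in them. The counts and p-values given are from the unblocked fit, which leaves this pairing out, unless a block is named. A fit with the replicate number as a block was the alternative.

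Alternatives were no background correction (raw signals under 1 set to 1), a median shift or cyclic loess in place of quantile normalization, the authors' processed values, no filter on dim probes, detection on all 18 arrays, every kept probe, the mean of a gene's probes, only the arrays compared, the replicate block, an intensity trend with a robust prior, array weights, a minimum of 2-fold, and each array left out in turn. The authors' values with a replicate block and the removal of each replicate set were added after the data had been seen. A block by chip was not run, because the sources used here name no chips.

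The procedure was tested on simulated data for 13505 genes with seeded changes. It recovered 81%, 81%, 76% and 81% of 2-fold changes for E2 in the ERα line, E2 in the ERβ line, doxycycline in the ERα line and doxycycline in the ERβ line, 59% and 58% for the E2 and doxycycline differences, and 76% for the lines without doxycycline, and 96%, 98%, 98%, 100%, 92%, 90% and 96% of 4-fold changes in the same order, but only 56%, 46%, 28%, 34%, 12%, 20% and 26% of 1.41-fold changes. False calls numbered 7, 10, 6, 10, 9, 2 and 4. A shifted list was called in all 7 comparisons and 0 of 20 unshifted lists were. Recovery depends on the number of calls, 115 to 164 in these simulations, so the shares are too high where far fewer genes are called. The simulated genes varied independently and carried no replicate effect, so this does not show how often lists of correlated genes are miscalled. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.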

Results

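Gene expression was measured in U2OS cells, a human osteosarcoma line, that had been stably transfected with a vector for estrogen receptor alpha (ERα) or beta (ERβ) under the control of doxycycline, an antibiotic that switches such vectors on. Each line was grown without doxycycline, with doxycycline, or with doxycycline plus E2, the common short name of the estrogen estradiol. The 6 groups held 3 single-colour Illumina arrays each, 18 arrays in all, and 13505 genes had a detected probe. Between 19834 and 22485 probes were detected per array, or 40.6% to 46.1% of those on the array, and the median raw signal was 217 to 251. The sources used here give no doses or treatment times. The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.139. The labels do not say that the 3 arrays of a group came from separate cultures, so all p-values measure only the spread between these arrays, which may be technical. Changes are log2 changes ± SE with 3 arrays per group, and p-values are from limma, adjusted over all genes. Each gene has 1 estimate of spread from all 18 arrays, so SE and p are too small where a compared group varied more. In ERβ cells with doxycycline the SD was 1.26 for FGF21, 0.84 for CXCL8 and TRIB3 and 0.74 for KRT19, against at most 0.34 in other groups. Over all genes the median residual SD without and with doxycycline was alike, 0.172 in the ERα line and 0.171 in the ERβ line.

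The receptor transcripts were examined first, to see whether doxycycline switched on the gene that each vector carries. ESR2, which encodes ERβ, stood at a log2 level of 11.26 ± 0.14 (SD, n = 3) in ERβ cells without doxycycline, at 15.94 ± 0.14 with doxycycline and at 16.04 ± 0.01 with doxycycline plus E2 (probe ILMN_2390457). The rise with doxycycline was 25.7-fold on the signal of this probe (log2 change 4.68 ± 0.22, adjusted p = 8.23e-10), which with doxycycline lay at 87.2% of the brightest probe of the array, near the top of the scale, where a rise may not show in full. A second ESR2 probe, ILMN_1740045, which reached 62.5% of the brightest probe, rose from 9.89 to 15.44, or 46.9-fold (adjusted p = 8.75e-11 over all kept probes), so the size of the rise depended on the probe. ERα cells without doxycycline showed no detected ESR2, and uninduced ERβ cells stood at least 31.2-fold above them (adjusted p = 2.66e-11), so ESR2 was already abundant in the ERβ line before induction. E2 did not change ESR2 in ERβ cells (0.10, adjusted p = 0.888), although the signal lay at 87.2% to 93.0% of the brightest probe in these groups. ESR1, which encodes ERα, had 1 probe (ILMN_1678535), which stayed near background in ERα cells at 6.22 ± 0.47 without doxycycline, 5.76 ± 0.29 with it and 6.34 ± 0.29 with E2 added (SD, n = 3). It was detected on 1, 0 and 2 of the 3 arrays in these groups and on none in the ERβ line. Its doxycycline change in ERα cells was -0.46 ± 0.23 (adjusted p = 0.976), and its fitted difference between uninduced ERβ and ERα cells was -1.32 ± 0.23 (adjusted p = 2.30e-04). The place of this probe in the transcript is not given in the sources used here, so it does not test whether doxycycline induced ERα. Here and below, a group in which a probe was undetected on all arrays gives only a bound, written as "at least" and set against the lowest signal detected on those arrays. The log2 change of such a gene is a fitted value, not a bound, and orders of changes are those of the fitted values, so the place of such a gene in them is not measured.

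**Figure D1:**
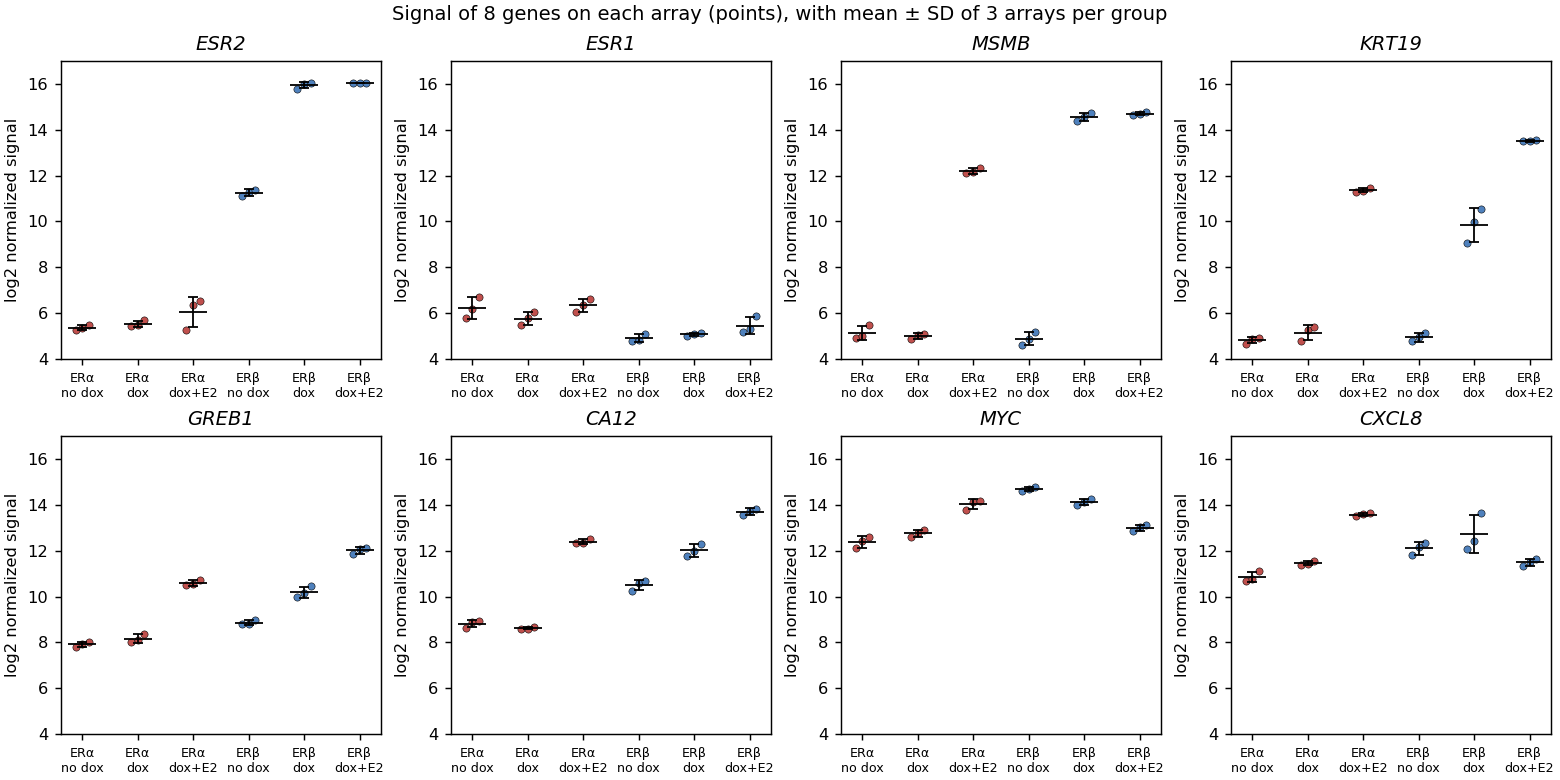
Normalized log2 signal (vertical axis) of ESR2, ESR1, MSMB, KRT19, GREB1, CA12, MYC and CXCL8 in the 6 groups; each point is 1 array and the bars give the mean ± SD of 3 arrays. ESR2 rises with doxycycline in the ERβ line to 15.94, MSMB rises with E2 in the ERα line and with doxycycline alone in the ERβ line, and MYC goes up with E2 in the ERα line and down in the ERβ line.

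The E2 comparison within the ERα line asked what E2 changes in cells that carry the ERα vector and were grown with doxycycline. MSMB, a secreted protein abundant in prostate fluid, rose at least 59.5-fold with E2 (7.21 ± 0.16, adjusted p = 1.89e-13). TH, the rate-limiting enzyme of catecholamine synthesis, rose at least 52.9-fold (6.72 ± 0.20), and KRT19, a keratin of simple epithelia, rose at least 33.2-fold (6.23 ± 0.26). OTOF, a calcium sensor of hair cell synapses, rose at least 34.9-fold (6.20 ± 0.12), and the receptor tyrosine kinase RET rose at least 25.1-fold (5.23 ± 0.18). The keratins KRT72 and KRT73 and the sulfotransferase CHST8 rose at least 19.9-fold, 21.9-fold and 17.1-fold. The largest fitted falls were those of HAS2, a hyaluronan synthase (-2.76 ± 0.20, adjusted p = 9.81e-08), BMF, a promoter of apoptosis (-2.74 ± 0.16), PLAU, the urokinase plasminogen activator (-2.52 ± 0.22), RGPD1 (-2.52, at least 4.34-fold), LMCD1 (-2.51), RGS16, which dampens G protein signalling (-2.30 ± 0.11), HRCT1 (-2.28) and FAM110D (-2.26). With E2, the HAS2 probe was detected on 1 of 3 arrays.

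In all, 2975 of the 13505 genes changed with E2 in the ERα line, 1475 up and 1500 down, and 746 of them changed at least 2-fold, 544 up and 202 down. Of 41 measured classical estrogen targets, fixed from work in breast cancer cells, 31 rose, 1 fell and 9 did not pass (32 and 1 adjusted over the list alone; median 1.36, camera adjusted p = 8.88e-25). Among them the surface carbonic anhydrase CA12 rose 13.8-fold (3.78 ± 0.14), GREB1, a growth regulator named for its induction by estrogen, rose 5.39-fold (2.43 ± 0.13; 2.21-fold on its probe ILMN_1715984), and the ADP-ribosyltransferase TIPARP rose by 1.71 ± 0.07. A list of 15 genes named in earlier receptor studies in U2OS cells had 10 rises and 1 fall (10 and 1 adjusted over the list alone; adjusted p = 4.01e-06). CCN5, a secreted regulator of smooth muscle growth, rose at least 4.40-fold and TMEM121B rose 8.52-fold within it. Both lists also passed with an estimated correlation between genes (adjusted p = 1.74e-06 and 0.0106), but the U2OS study list did not pass over the genes detected on all 18 arrays (0.516). Here and below, that setting drops members undetected in any group, among them MSMB, KRT19 and CCN5. It therefore tests only the remaining members. Of 33 DNA replication and E2F target genes, 17 rose and none fell (23 and 0 adjusted over the list alone; camera adjusted p = 1.53e-08, but adjusted p = 0.149 with an estimated correlation). They included the helicase subunit MCM2 (0.71), the transcription factor E2F2 (0.92) and the chromatin assembly factor subunit CHAF1A (0.74). Of 26 nuclear receptor cofactors and sister receptors, 8 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0446), among them the retinoic acid receptor RARA (1.37) and GPER1, a membrane estrogen receptor (1.25). That call was lost with an estimated correlation (adjusted p = 0.244), with replicates as a block (0.0571), with a median shift (0.0995), with cyclic loess (0.0619) and with the mean of a gene's probes (0.104). It was also lost without ERα doxycycline array 4 (0.0679) or 5 (0.0513) and without ERα E2 array 9 (0.0703), and without replicate set 1 (0.0901) or 3 (0.0631).

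The other lists did not pass for E2 in the ERα line, although some members changed. In the bone list 5 of 18 genes rose and 3 fell, with rises of the growth factor BMP2 (1.79 ± 0.15) and the parathyroid hormone receptor PTH1R (3.24, detected on 2 of 3 arrays without E2) and a fall of RUNX2, the master regulator of osteoblasts (-1.32 ± 0.11). In the NF-kB and cytokine list 5 of 20 rose and 1 fell (camera adjusted p = 0.183), led by the neutrophil chemoattractant CXCL8, which rose 4.38-fold (2.13 ± 0.29). The TGF-beta and YAP list was split, with 4 rises and 6 falls among 24 genes, such as CCN1 (1.80) against TGFBI and ID1 (both -1.53). The ATF4 list had 2 rises and 6 falls among 29, with a fall of the mTOR inhibitor DDIT4 (-1.91). Only 2 of 30 proliferation genes passed (camera adjusted p = 0.919), and none of 32 ribosomal protein genes did. The immediate-early list had 3 rises and 4 falls among 25, with MYC up 2.43-fold (1.28 ± 0.13, adjusted p = 3.59e-06). The heat shock list had 2 rises and 2 falls among 22, the p53 list 5 and 2 among 22, and the cholesterol list 3 and 0 among 24. Of the markers of other cell types, 2 of 8 blood, 1 of 8 endothelial and 2 of 13 epithelial genes rose, 2 epithelial genes fell, and the fibroblast list had 2 rises and 4 falls among 12. Adjusted over the list alone, the counts of rises and falls were 6 and 1 for NF-kB, 5 and 6 for TGF-beta and YAP, 4 and 5 for immediate-early genes and 2 and 4 for epithelial markers, and those of the other lists in this paragraph did not change. The count of 2975 was 4683 with the authors' processed values, 1458 without the 6 arrays of replicate set 1 and 1765 without those of set 2.

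The same comparison in the ERβ line asked what E2 adds in cells with induced ERβ. CMKLR1, the receptor for chemerin, rose by a fitted 4.44 ± 0.25 on the log2 scale (adjusted p = 2.28e-08), and PDZK1, a scaffold protein of membrane transporters, by a fitted 4.12 ± 0.21. Without E2 their probes were detected on 2 and 1 of 3 arrays, near the detection limit. The lysophosphatidic acid receptor LPAR1 rose 15.8-fold (3.98 ± 0.18), TMEM121B 13.8-fold, KRT19 12.7-fold (3.66 ± 0.26) and the prostaglandin transporter SLCO2A1 10.9-fold (3.45 ± 0.12). CYP1A2, a liver enzyme of drug metabolism, rose at least 6.04-fold, and PLA2G4D, a phospholipase, at least 9.57-fold. The largest fitted falls were those of the growth factor TGFB2 (at least 3.16-fold, adjusted p = 5.85e-06), which was undetected with E2, the cytokine IL6 (-1.83 ± 0.20), TRIM47 (-1.76), the BMP antagonist NOG (-1.68), PLAU (-1.62 ± 0.22), FGF2 (-1.59), RIPPLY2 (-1.53) and DMBT1 (-1.52). With E2, the RIPPLY2 probe was detected on 1 of 3 arrays.

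E2 changed 1867 genes in the ERβ line, 943 up and 924 down, and 391 at least 2-fold, 323 up and 68 down. Of the 41 classical estrogen targets, 22 rose and 1 fell (22 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 6.90e-16, and 2.02e-05 with an estimated correlation). GREB1 rose 3.58-fold (1.84 ± 0.13; 6.07-fold on its probe ILMN_1736956), TIPARP by 1.60 and the lipid transporter ABCA3 by 2.87, its probe being detected on 1 of 3 arrays without E2. The U2OS study list had 5 rises and 2 falls among 15 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0120, but adjusted p = 0.134 with an estimated correlation, 0.0525 without ERβ E2 array 9, 0.0502 without replicate set 3 and 0.708 over the genes detected on all 18 arrays). The cofactor list had 5 rises and 1 fall among 26 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00634, but adjusted p = 0.134 with an estimated correlation). Its risers included NRIP1, a corepressor bound by estrogen receptors (1.36), and the coactivator NCOA1 (1.04). NRIP1, like RARA named above for the ERα line, is also among the classical estrogen targets, so the 2 lists are not separate evidence. In the immediate-early list 6 genes rose and 5 fell, with falls of MYC (-1.12 ± 0.13, adjusted p = 3.10e-05) and KLF6 (-1.24). CXCL8 was lower with E2 (-1.23 ± 0.29, adjusted p = 0.00846), a call lost when only the arrays compared were fitted and without replicate set 1. The NF-kB list had 2 rises and 4 falls, and the interferon list had 4 falls with no rise, as for the antiviral gene RSAD2 (-1.03). The epithelial list had 3 rises among 13 (camera adjusted p = 0.0933), with the mucin MUC1 at 2.39 and the pioneer factor FOXA1 at 1.52 (detected on 2 of 3 arrays without E2). Replication and proliferation genes passed in 1 case each, and no ribosomal protein gene did. Adjusted over the list alone, the rises and falls were 7 and 6 for immediate-early genes, 5 and 5 for NF-kB, 0 and 0 for proliferation, and 5 and 7 for the 24 genes of the TGF-beta and YAP list, which had 4 and 5 over all genes. Those of the other lists in this comparison did not change. The total of 1867 was 3180 with the authors' values, 3683 with array weights, 1070 with only the arrays compared, and 653 and 1026 without replicate sets 1 and 2.

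Whether the E2 responses of the lines differed was tested directly, as the ERβ change minus the ERα change. The response of MSMB was far smaller in the ERβ line (-7.06 ± 0.22, adjusted p = 7.84e-11): its level was already 14.56 ± 0.18 with doxycycline alone and 14.71 ± 0.06 with E2 (SD, n = 3). TH (-5.17 ± 0.28), RET (-4.35 ± 0.26), KRT73 (-4.29 ± 0.21), RIPOR2 (-4.16 ± 0.28) and KRT72 (-4.06 ± 0.24) followed. All 6 probes were undetected in ERα cells with doxycycline alone, so the sizes of these differences are fitted values. In the other direction stood PKD2L1, an ion channel (fitted 2.99 ± 0.30), TMCC2 (2.89 ± 0.30), the transcription factor STAT4 (2.83 ± 0.26), RGS16 (2.8 ± 0.16), HAS2 (2.7 ± 0.29) and SYNPO2L (2.35 ± 0.25). PKD2L1 was detected only in ERβ cells with E2, on 3 of 3 arrays, so its size and place in this order rest on background levels, and TMCC2 was detected on 1 of 3 ERβ arrays with doxycycline alone. HAS2 was near the detection limit in ERβ cells with doxycycline alone (2 of 3 arrays) and in ERα cells with E2 (1 of 3), so a further fall in ERβ cells could not be seen and its difference is a fitted value too. STAT4 went from 6.50 ± 0.21 to 9.49 ± 0.06 with E2 in ERβ cells (SD, n = 3). MYC (-2.41 ± 0.19, adjusted p = 9.23e-07) and CXCL8 (-3.36 ± 0.40, adjusted p = 7.05e-05) differed with opposite changes in the lines, and BMP2 (-2.44 ± 0.21) and CCN1 (-2.58) had lower changes in ERβ cells. For GREB1 the responses did not differ past the threshold (-0.59, adjusted p = 0.0625), and the value depended on the probe and the setting. Its other kept probes had fitted changes of 1.15 in ERα cells and 1.81 in ERβ cells (ILMN_1715984) and of 2.5 and 2.6 (ILMN_1736956, undetected in ERα cells with doxycycline alone), differences not tested by probe, and the mean of the probes gave 0.06 (adjusted p = 0.952). The chosen probe passed with replicates as a block (adjusted p = 0.0108), with array weights (0.0308), over the genes detected on all 18 arrays (0.0490) and without ERα doxycycline array 4 (0.0342) or ERβ doxycycline array 5 (0.0253), and had adjusted p up to 0.525 under the other settings. KRT19, undetected in ERα cells with doxycycline alone, differed by a fitted -2.56 ± 0.37 (adjusted p = 3.73e-04), which was lost without background correction, without replicate set 1 and with the authors' values when replicates were a block (adjusted p = 0.0564).

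In total 1174 genes had different E2 responses, 455 with a higher and 719 with a lower change in the ERβ line. Of the 41 classical targets, 13 had a lower and 2 a higher change (16 and 3 adjusted over the list alone; camera adjusted p = 1.02e-07, and 8.03e-04 with an estimated correlation). The U2OS study list had 5 lower and 1 higher among 15 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00212, but adjusted p = 0.0809 with an estimated correlation, 0.0675 with the authors' values and 0.757 over genes detected on all 18 arrays). Of 33 replication genes 5 were lower (15 adjusted over the list alone; camera adjusted p = 8.30e-07, but adjusted p = 0.155 with an estimated correlation), such as MCM2 (-0.81), which was lost without replicate set 1. Epithelial markers (2 of 13 higher, 3 adjusted over the list alone) and fibroblast markers (3 of 12 higher, 3 adjusted over the list alone) passed camera with adjusted p = 0.00603 and 0.0130, but had adjusted p = 0.101 and 0.0809 with an estimated correlation. The epithelial call was lost without the filter on dim probes (0.141). MUC1 (2.14) was among the epithelial genes.

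The NF-kB and cholesterol lists had lower changes in the ERβ line, each with camera adjusted p = 0.0362, and neither call was firm. The NF-kB list (1 higher and 4 lower of 20, 1 and 4 adjusted over the list alone) had adjusted p = 0.877 with an estimated correlation and 0.0566 with replicates as a block. It was lost without ERα doxycycline array 4 (0.0550) or 5 (0.0592), ERα E2 array 7 (0.0588) or 9 (0.0651), ERβ doxycycline array 5 (0.253), or ERβ E2 array 7 (0.107). The cholesterol list (1 lower of 24, none adjusted over the list alone) had adjusted p = 0.234 with an estimated correlation. It was lost without ERα doxycycline array 5 (0.0592), ERα E2 array 7 (0.0627), ERβ doxycycline array 6 (0.0695) or ERβ E2 array 7 (0.0588). Without replicate sets 1 and 2 both were lost (0.133 and 0.229 for NF-kB, 0.0973 and 0.0614 for cholesterol). The 1174 differing genes became 2495 with the authors' values, 2435 with array weights, and 305, 585 and 682 without replicate sets 1, 2 and 3.

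The overlap of the E2 responses, whose arrays are separate, asked how many genes the lines share. Of the genes called in both lines, 984 moved the same way, 602 up and 382 down, against 103 and 103 for independent lists, and 112 moved in opposite directions. The genes that moved the same way made up 52.7% of the ERβ calls and 33.1% of the ERα calls. The correlation of the changes across all genes was 0.56 (0.01 for simulated unchanged groups). Genes are not independent replicates. CMKLR1 rose by 4.54 in ERα cells and 4.44 in ERβ cells, PDZK1 by 4.11 and 4.12, and LPAR1 by 3.80 and 3.98. In ERα cells without E2, CMKLR1 and PDZK1 were undetected, as was IL12A below. PLAU and BMF fell in both, and the cGMP phosphodiesterase PDE5A fell too (-1.18 and -1.12). CDK5R1, an activator of a neuronal kinase, changed by 1.30 in ERα cells and -1.35 in ERβ cells, IL12A changed by 1.83 and -0.98, the neurotrophin BDNF by 1.20 and -0.90, and the chemokine CX3CL1 by -1.18 and 1.06. The 984 became 1707 with the authors' values, 1690 with array weights and 361 and 496 without replicate sets 1 and 2.

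Doxycycline alone was compared in each line to ask what doxycycline, meant to induce the receptor, changes without added E2. No array had doxycycline without a receptor vector. In the ERα line 2 genes passed: the stress-induced transcription factor ATF3 rose 2.05-fold (1.04 ± 0.09, adjusted p = 1.11e-04) and the Src family kinase FYN fell (-1.35 ± 0.12, adjusted p = 1.11e-04). Both calls were lost when only the arrays compared were fitted (0 genes, adjusted p = 0.134) and without replicate set 1 or 2. GREB1 (0.25, adjusted p = 0.991), KRT19 (0.32) and CCN5 (0.04) did not pass. With an unadjusted p under 0.05 the count was 705, with the authors' values 34 and with array weights 7. The self-test on simulated data recovered 28% of 1.41-fold, 76% of 2-fold and 98% of 4-fold changes in this comparison. Small changes would thus mostly not have been called. With its 145 calls the adjusted threshold was easier to pass than with 2, so these rates are too high for the real arrays. Larger changes may have been missed too: FGF21 went from 5.69 (undetected) to 7.80 (detected on 3 of 3 arrays) and was not called.

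Several lists shifted in the ERα line with doxycycline although few or none of their members passed alone, and none of these calls held with an estimated correlation. The ATF4 and amino-acid stress list was higher with a median of 0.40 (1 of 29 rose, 14 adjusted over the list alone; camera adjusted p = 9.81e-23, but adjusted p = 0.142 with an estimated correlation). The NF-kB list was higher (0 of 20, 1 adjusted over the list alone; camera adjusted p = 5.86e-06), as was the immediate-early list (1 of 25, 2 adjusted over the list alone; camera adjusted p = 5.37e-04). The proliferation list was lower with a median of -0.11 (0 of 30, 1 adjusted over the list alone; camera adjusted p = 1.24e-04), a call lost without ERα no-doxycycline array 1 (0.0661). For the last 3 lists the adjusted p was 0.231 with an estimated correlation. The p53 list (higher, camera adjusted p = 0.0448), the cholesterol list (lower, 0.0448) and the blood cell markers (lower, 0.0410) had adjusted p = 0.142, 0.231 and 0.142 with an estimated correlation, and no member passed over all genes (1 p53 gene rose, adjusted over the list alone). Each was lost without some single arrays. For p53 these were ERα no-doxycycline arrays 2 (0.357) and 3 (0.0670) and ERα doxycycline arrays 4 (0.105) and 6 (0.115). For cholesterol they were ERα no-doxycycline array 1 (0.677) and ERα doxycycline arrays 4 (0.0754) and 5 (0.178), and for blood ERα no-doxycycline array 3 (0.303) and ERα doxycycline arrays 5 (0.0689) and 6 (0.105). The p53 call was also lost with a median shift (0.120), the cholesterol and blood calls without the filter on dim probes (0.0723 and 0.192), and all 3 with the mean of a gene's probes (0.0512, 0.118 and 0.116). Without a replicate set, p53 was lost for sets 2 and 3 (0.166 and 0.117), cholesterol for sets 1 and 2 (0.735 and 0.150) and blood for set 3 (0.580).

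In the ERβ line doxycycline changed many genes. MSMB rose at least 283-fold (9.67 ± 0.16, adjusted p = 5.20e-15), CCN5 at least 31.4-fold (5.85 ± 0.14) and F13A1, a subunit of clotting factor XIII, at least 29.6-fold (5.26 ± 0.16). The protease inhibitor CST1 rose at least 24.7-fold and its relative CST5 rose by a fitted 5.16 on the log2 scale, with a mean level below the detected range and detection on 1 of 3 arrays without doxycycline. The ubiquitin ligase MARCHF4 rose 31.8-fold, MAP7D2 at least 14.8-fold, KRT73 at least 16.4-fold and KRT19 at least 10.9-fold. GREB1 rose 2.51-fold on its chosen probe (1.33 ± 0.13, adjusted p = 2.61e-06), but its probe ILMN_1715984 rose 1.47-fold and did not pass (adjusted p = 0.121 over all kept probes), and ILMN_1736956, undetected without doxycycline on all 3 arrays, did (adjusted p = 0.00200). The largest fitted falls were those of GABRR1, a GABA receptor subunit (-3.45 ± 0.21, adjusted p = 1.16e-08), FCRL4 (at least 4.53-fold), the metalloprotease ADAMTS20 (-3.20 ± 0.17), the lens crystallin CRYBA4 (at least 6.03-fold), the metabolic hormone FGF21 (-2.71 ± 0.42, and -3.44 without ERβ doxycycline array 5), IQGAP2 (-2.55), HAS2 (-2.43 ± 0.20) and SYNPO2L (-2.42). With doxycycline, the FCRL4 and CRYBA4 probes were undetected and the FGF21 and HAS2 probes were each detected on 2 of 3 arrays.

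The ERβ line had 2776 calls with doxycycline, 1337 up and 1439 down, of which 615 were at least 2-fold, 419 up and 196 down. The U2OS study list had 9 rises and 1 fall among 15 genes (10 and 1 adjusted over the list alone; median 0.90, camera adjusted p = 5.32e-09, and 0.00357 with an estimated correlation), with a rise of KLRC2, a natural killer cell receptor (3.80), and a fall of the bone-protecting decoy receptor TNFRSF11B (-2.39 ± 0.12). Over the genes detected on all 18 arrays that list did not pass (0.0972). Of the classical targets 16 rose and 4 fell (17 and 6 adjusted over the list alone; camera adjusted p = 3.25e-05, and 0.00396 with an estimated correlation), such as the growth factor TGFA (3.21) and SERPINA1, a blood protease inhibitor (3.28). ATF4 and amino-acid stress genes fell together: 22 of 29 fell and none rose (25 and 0 adjusted over the list alone; median -0.93, camera adjusted p = 4.79e-11, but adjusted p = 0.196 with an estimated correlation). Among them were the stress cytokine GDF15 (-1.87 ± 0.19), the serine synthesis enzyme PSAT1 (-1.31 ± 0.15) and the mitochondrial enzyme PCK2 (-1.29). Of 29 interferon-stimulated genes 12 rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 4.83e-08, but adjusted p = 0.30 with an estimated correlation). RSAD2 rose 8.26-fold (3.05 ± 0.15), the antiviral OASL by 2.43 and the exonuclease ISG20 by 2.34.

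Fibroblast markers also fell with doxycycline in the ERβ line, 7 of 12 with no rise (9 and 0 adjusted over the list alone; camera adjusted p = 2.05e-04, and 0.0106 with an estimated correlation), as for the calcium-binding protein S100A4 (-0.91). Of 33 replication genes 10 fell and none rose (14 and 0 adjusted over the list alone; median -0.19, camera adjusted p = 0.00189, but adjusted p = 0.469 with an estimated correlation). Blood cell markers rose in 3 of 8 cases (3 adjusted over the list alone; camera adjusted p = 0.0183, but adjusted p = 0.0786 with an estimated correlation), with the lysosomal protein LAPTM5 at least 3.34-fold higher and the B-cell receptor component CD79A at 1.70 ± 0.19 (detected on 2 of 3 arrays without doxycycline). That call was lost without the filter on dim probes (0.126) and without replicate set 3 (0.131). The collagen and matrix list (6 up and 6 down of 29), the TGF-beta and YAP list (6 and 6 of 24) and the immediate-early list (5 and 6 of 25) went both ways and did not pass. No endothelial marker and 3 of 32 ribosomal protein genes passed, the latter all down. Adjusted over the list alone, the falls were 7 for each of the collagen and TGF-beta lists and 1 for ribosomal proteins, with the other counts as given. The 2776 became 4648 with the authors' values, 4177 with array weights, 1548 with only the arrays compared, and 1017 and 1418 without replicate sets 1 and 2.

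**Figure D2:**
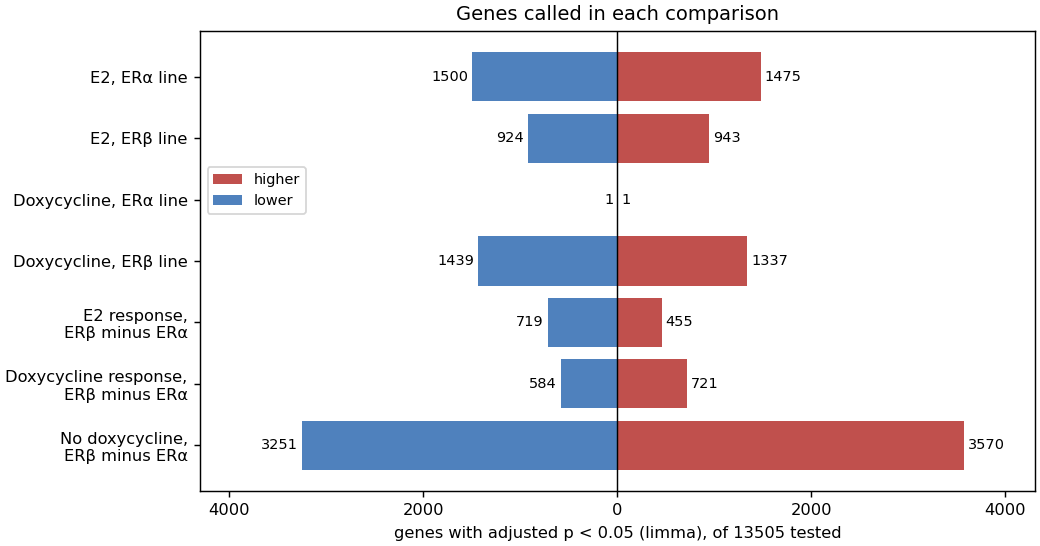
Number of genes called higher and lower (horizontal axis, count of genes at adjusted p under 0.05) in each comparison of 3 arrays against 3 and in the differences between lines (vertical axis). The bars show 2975 and 1867 genes for E2 in the ERα and ERβ lines against 2 and 2776 for doxycycline.

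The doxycycline responses were then compared between the lines, as ERβ minus ERα. MSMB (9.81 ± 0.22, adjusted p = 6.58e-13), CST1 (6.10 ± 0.29), F13A1 (5.94 ± 0.22), CCN5 (5.81 ± 0.19), the transglutaminase TGM2 (5.48 ± 0.17) and CST5 (5.45 ± 0.35) had the largest positive differences. FGF21 (-4.83 ± 0.59, adjusted p = 5.28e-05, and -5.55 without ERβ doxycycline array 5), ADAMTS20 (-3.88 ± 0.24), the peptide hormones CALCB (-3.48 ± 0.38) and VIP (-3.01 ± 0.35), FCRL4 (-3.07 ± 0.30) and GABRR1 (-2.89 ± 0.30) had the largest negative ones. These are fitted values: MSMB, CST1, F13A1 and CCN5 were undetected in ERβ cells without doxycycline, CALCB, FCRL4 and VIP in ERβ cells with it, and FGF21 and CALCB in ERα cells without it. ESR2 differed by 4.51 ± 0.32, GREB1 by 1.08 ± 0.18 on its chosen probe (adjusted p = 0.00110, lost without replicate set 1) and ATF3 by -1.37. In all 1305 genes differed, 721 higher and 584 lower in the ERβ line, and 1969 did with replicates as a block. Of the 29 ATF4 list genes 22 had a lower change in the ERβ line (25 adjusted over the list alone; median -1.30, camera adjusted p = 3.26e-20, and 0.0452 with an estimated correlation), such as GDF15 (-2.79) and PSAT1 (-1.91). The U2OS study list (9 higher and 1 lower of 15, 10 and 1 adjusted over the list alone) and the classical targets (14 and 3 of 41, 16 and 5 adjusted over the list alone) had camera adjusted p = 2.25e-10 and 2.09e-06, and both had 0.00149 with an estimated correlation. The former did not pass over genes detected on all 18 arrays (0.0772).

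Interferon genes had higher changes in the ERβ line (10 of 29, 11 adjusted over the list alone; camera adjusted p = 1.78e-08, but adjusted p = 0.274 with an estimated correlation), led by RSAD2 (fitted 3.26, undetected in the ERα line) and OASL (2.74). Blood cell markers were higher in 3 of 8 cases (3 adjusted over the list alone; camera adjusted p = 0.00103, and 0.0179 with an estimated correlation), and fibroblast markers were lower in 4 of 12 (6 adjusted over the list alone; 0.00206, and 0.0249 with an estimated correlation). The replication list was lower with 1 gene of 33 called (0 adjusted over the list alone; camera adjusted p = 0.0345, but adjusted p = 0.788 with an estimated correlation). It was lost without ERα no-doxycycline array 3 (0.0882), ERα doxycycline array 5 (0.0796), ERβ no-doxycycline array 1 (0.0825) or 2 (0.0546), or ERβ doxycycline array 5 (0.176), without replicate set 2 (0.335), and over the genes detected on all 18 arrays (0.0526). The count of 1305 was 2759 with the authors' values, 2003 with array weights, and 411 and 660 without replicate sets 1 and 2.

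Whether E2 acted on the genes that doxycycline had already moved was asked within each line. In the ERβ line 843 genes were called in both steps. Of these 703 moved the same way, 396 up and 307 down, against 93.4 and 98.5 for independent lists, and 140 moved in opposite directions. KRT19 rose by 4.90 with doxycycline and by a further 3.66 with E2, OTOF by 3.19 and 3.23, and the taste receptor TAS1R1 by 2.82 and 2.95 (fitted values for the doxycycline step of KRT19 and TAS1R1, undetected before it). IL6 (-1.43 and -1.83) and NOG (-1.19 and -1.68) fell in both steps. TRIM47 (1.44 and -1.76), CDK5R1 (2.54 and -1.35) and the Wnt receptor FZD4 (1.69 and -1.10) rose and then fell. Both steps use the doxycycline arrays with opposite sign: the correlation across genes was 0.28, against -0.50 for simulated unchanged groups, and the covariance was 0.0590 against -0.0217, a difference of 0.0807. The 3 arrays could not be divided into parts of at least 2. The sharing pushes the steps towards opposite signs, so part of the 140 opposite calls may come from it. In the ERα line neither ATF3 nor FYN was called for E2 (0 genes in both, 0.11 per direction for independent lists; correlation -0.09 against -0.50 simulated, covariance -0.00932 against -0.0215). The 843 became 1701 with the authors' values, 1690 with array weights, and 219 and 361 without replicate sets 1 and 2. The 0 became 21 with the authors' values, 3 with array weights, 2 with every probe, and 1 without ERα no-doxycycline array 2 or ERα doxycycline array 5.

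E2 in the ERα line and doxycycline alone in the ERβ line, which share no arrays, were set side by side after the results had been seen. There were 1034 genes called in both with the same direction, 563 up and 471 down, against 146 and 160 for independent lists, and 160 with opposite directions. MSMB rose by 7.21 and 9.67, KRT72 by 5.38 and 4.89, F13A1 by 4.84 and 5.26, and the arginine deiminase PADI4 by 4.90 and 4.63. HAS2 fell in both (-2.76 and -2.43), as did RGS16 (-2.30 and -2.11). CCL2, a monocyte chemoattractant, changed by 0.96 and -1.90, and the ephrin receptor EPHA4 by -1.52 and 3.01. The sizes are fitted: MSMB, KRT72 and PADI4 were undetected before both rises, and F13A1 and EPHA4 in ERβ cells without doxycycline. The correlation across all genes was 0.50.

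**Figure D3:**
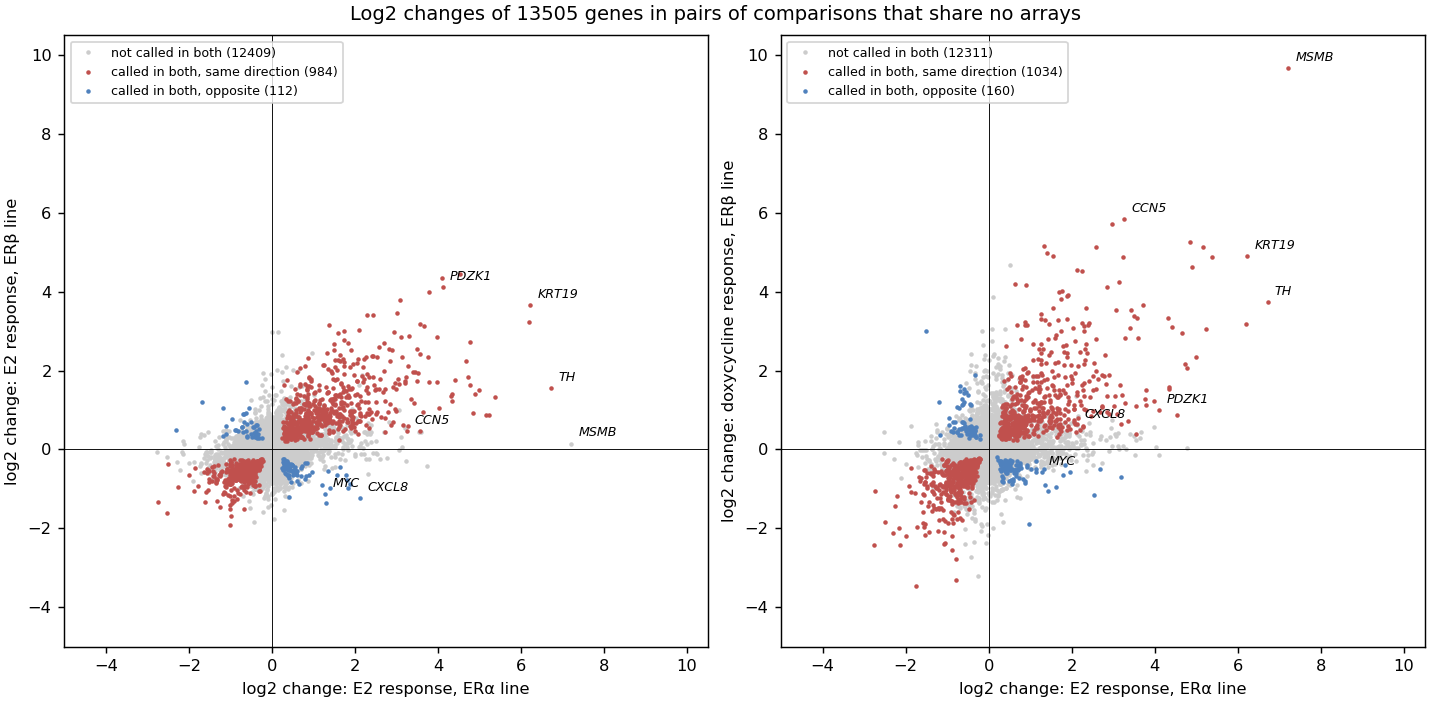
Log2 changes of all 13505 genes: E2 in the ERα line (horizontal axis) against E2 in the ERβ line and against doxycycline alone in the ERβ line (vertical axes); each point is 1 gene and the coloured points were called in both comparisons. MSMB lies at 7.21 and 9.67 in the panel for doxycycline, while its E2 change in the ERβ line (0.15) did not pass.

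The lines were also compared without doxycycline, to see how far they differed before induction. The serotonin-gated channel HTR3A stood 53.5-fold higher in uninduced ERβ cells than in uninduced ERα cells (5.74 ± 0.17), the antiviral membrane protein BST2 46.9-fold (5.55 ± 0.14), the small heat shock protein HSPB3 by 5.50 on the log2 scale and the hexokinase HKDC1 by 5.49. In uninduced ERα cells the HSPB3 probe was detected on 2 of 3 arrays and the HKDC1 probe on 1, near the detection limit. TNFAIP6, a hyaluronan-binding protein induced by inflammation, was lower (-7.00 ± 0.22, detected on 1 of 3 uninduced ERβ arrays), as were the IL-13 decoy receptor IL13RA2 (-6.56 ± 0.12, at least 33.3-fold), CRYGS (-6.43), VAMP5 (at least 23.0-fold) and the lipocalin APOD (-5.72). GREB1 was higher in ERβ cells by 0.95 on its chosen probe (adjusted p = 2.22e-05), but its other kept probes did not pass (0.26 and 0.09, adjusted p = 0.396 and 0.801 over all kept probes). In all 6821 genes, or 50.5%, differed, 3570 higher and 3251 lower, and 1856 of these at least 2-fold.

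Proliferation genes were higher in uninduced ERβ cells in 29 of 30 cases and replication genes in 29 of 33, with none lower (29 in each adjusted over the list alone; camera adjusted p = 5.24e-11 for both, but adjusted p = 0.0678 for both with an estimated correlation), such as RRM2, which makes deoxynucleotides (1.90), and the replication licensing factor CDC6 (1.67). Of 29 ATF4 list genes 24 were higher and none lower (24 and 1 adjusted over the list alone; camera adjusted p = 8.45e-10, but adjusted p = 0.174 with an estimated correlation), with GDF15 at 4.90 and the folate enzyme MTHFD2 at 2.11. Of 29 interferon-stimulated genes 20 were higher (21 and 1 adjusted over the list alone; camera adjusted p = 1.83e-07, but adjusted p = 0.204 with an estimated correlation), such as IFIT3 (4.22) and RSAD2 (at least 6.20-fold). Collagen and matrix genes were lower in 25 of 29 cases and higher in 2 (25 and 2 adjusted over the list alone; camera adjusted p = 1.16e-10, but adjusted p = 0.0678 with an estimated correlation), as for COL8A1 (-4.58), COL11A1 (-3.62) and the gelatinase MMP2 (-2.18), and in the bone list COL1A1 was lower by a log2 change of -5.22.

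Markers of fibroblasts (7 of 12 lower, 2 higher), of epithelial cells (8 of 13 lower, 1 higher) and the cholesterol list (10 of 24 lower, 2 higher) had camera adjusted p = 0.00778, 0.0186 and 0.0186, and adjusted p = 0.0678, 0.162 and 0.162 with an estimated correlation, and their counts were the same adjusted over the list alone. The mitochondrial respiratory chain list was higher, with 11 up and 2 down of 29 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0186, but adjusted p = 0.341 with an estimated correlation). The TGF-beta and YAP list was lower, with 11 down and 5 up of 24 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0320, but adjusted p = 0.162 with an estimated correlation, 0.0559 with the mean of a gene's probes and 0.0527 without replicate set 3). Without single replicate sets the cholesterol call (0.0505 without set 1) and the epithelial call (0.0684 without set 3) were lost too. Classical estrogen targets went both ways, 14 higher and 10 lower, and did not pass (camera adjusted p = 0.597). The cofactor list (3 up and 13 down of 26), the p53 list (2 and 9 of 22) and the heat shock list (7 and 4 of 22) did not pass either. With 1 line per receptor, the receptor and the line cannot be told apart in any comparison between lines.

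**Figure D4:**
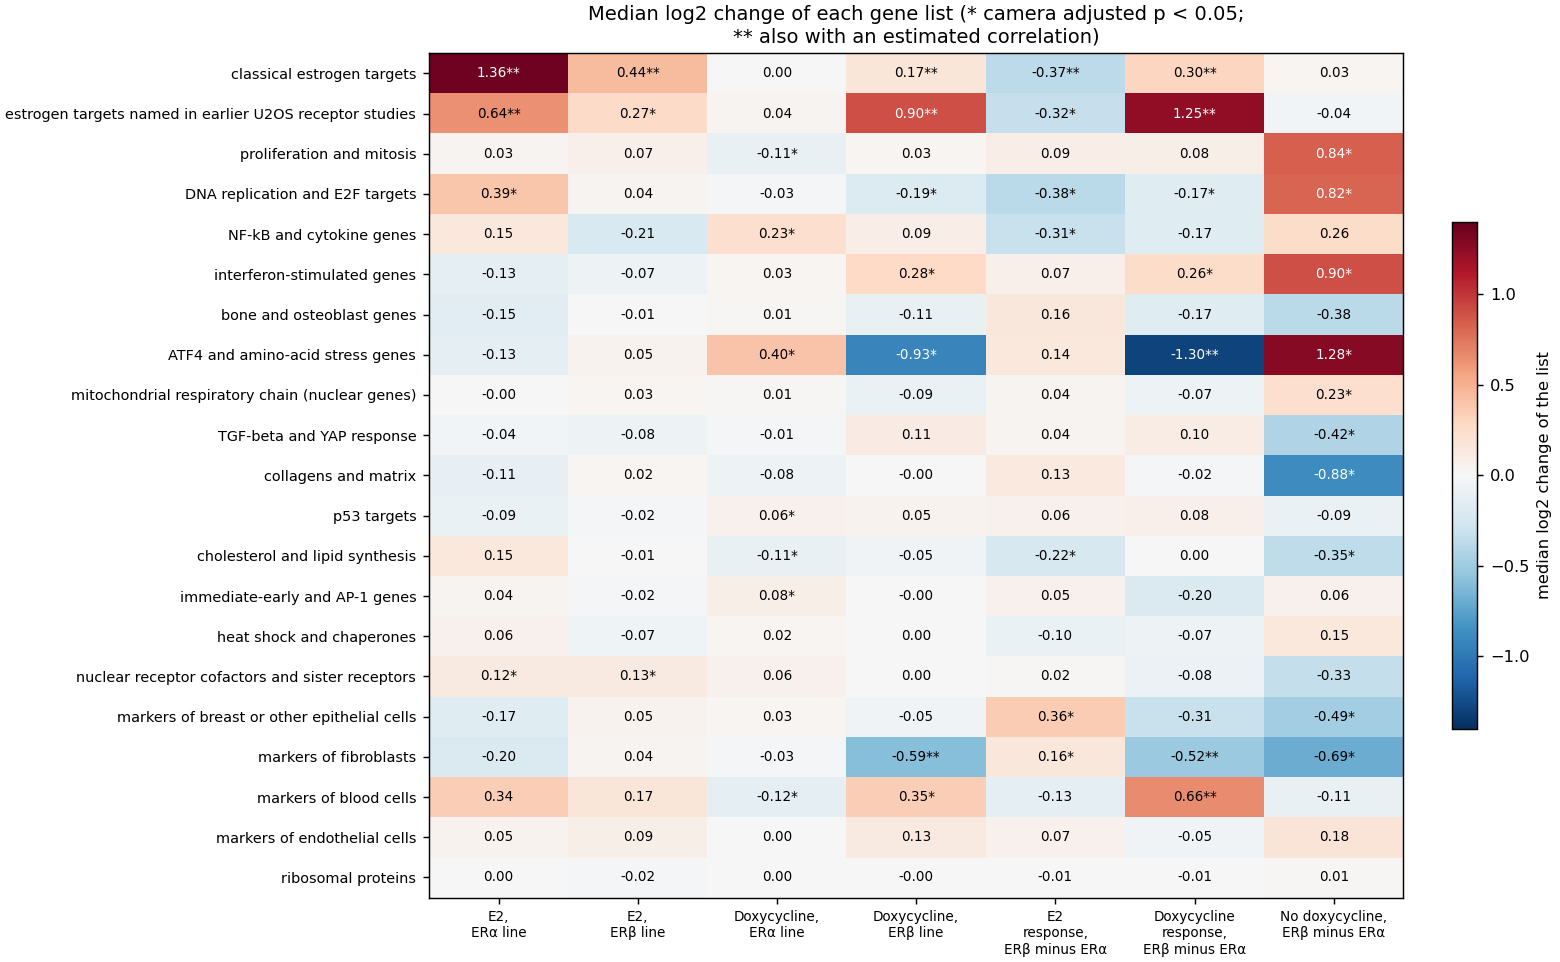
Median log2 change (colour scale) of each of the 21 gene lists (vertical axis) in each comparison (horizontal axis); 1 star marks camera adjusted p under 0.05 and a second star marks that the call also held with an estimated correlation. The classical estrogen targets rise with E2 in both lines, and the median of the ATF4 list is higher in uninduced ERβ cells and lower with doxycycline there, calls lost with an estimated correlation (adjusted p = 0.174 and 0.196).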

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

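The tests of ESR1, of ESR2 between the lines, of the ATF4 list, of genes outside the responses and of the uninduced ERβ arrays divided into separate parts, and the closer looks at the splits of the differences, were chosen after the results had been seen; the other tests in this part were planned.

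The response to E2 differed between the lines for 1174 genes (limma, ERβ minus ERα). The largest positive differences were those of PKD2L1 (2.99), TMCC2 (2.89), STAT4 (2.83), RGS16 (2.8), HAS2 (2.7) and SYNPO2L (2.35), and the largest negative ones those of MSMB (-7.06), TH (-5.17), RET (-4.35), KRT73 (-4.29), RIPOR2 (-4.16) and KRT72 (-4.06). A further 44 named genes passed, and so did 7 gene lists, of which only the classical targets held with an estimated correlation (adjusted p = 8.03e-04, and 0.0809 to 0.877 for the others). All sizes in this paragraph are fitted values, and several rest on groups in which the probe was undetected, as for PKD2L1, MSMB and CALCB. The response to doxycycline differed for 1305 genes, led by MSMB (9.81), CST1 (6.10), F13A1 (5.94), CCN5 (5.81), TGM2 (5.48) and CST5 (5.45) on one side and FGF21 (-4.83), ADAMTS20 (-3.88), CALCB (-3.48), FCRL4 (-3.07), VIP (-3.01) and GABRR1 (-2.89) on the other, with 47 further named genes and 7 lists, of which the interferon and replication lists were lost with an estimated correlation (adjusted p = 0.274 and 0.788).

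Of 100 splits of the arrays drawn within each line, the true one included, 8 gave as many genes for the E2 difference (highest other 2001) and 7 for the doxycycline difference (highest other 1683), so these counts alone do not exclude chance. Among the 17 that part all same-numbered arrays, as the true split does, the highest others were 1497 and 1525. All 7 and 6 other splits as large kept the true groups in one line and mixed them in the other, which points to the response of that line. The 82 and 80 splits that were true in neither line gave at most 1 gene. When same-numbered arrays were subtracted first, the true grouping of the paired differences called 1309 and 1074 genes and the highest of the other 9 groupings called 0, out of 10. For comparisons of 3 arrays against 3 the 10 splits are too few for a share under 0.05. Only 1 split, the true one, gave the real count each time: 2975 for E2 in the ERα line (highest other 0), 1867 for E2 in the ERβ line (1), 2 for doxycycline in the ERα line (1), 2776 for doxycycline in the ERβ line (0) and 6821 between the uninduced lines (0).

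Doxycycline changed 2 genes in the ERα line and 2776 in the ERβ line, and noise on the ERα arrays is argued against as the whole reason: the ERβ changes added to the ERα doxycycline arrays gave 2512 calls (1717 when they replaced the ERα changes), against 1548 on the ERβ arrays fitted alone. Doxycycline itself, without the receptor, is argued against as the source of the ERβ changes only if doxycycline was labelled correctly within the ERα line. The slope of the ERα on the ERβ changes was -0.000925 (-0.00638 to 0.00297 without 1 array) over the genes called in the ERβ line. An exchange of arrays between the lines is argued against, since ESR2 on the lowest of the 9 ERβ arrays lay 4.59 on the log2 scale above the highest of the 9 ERα arrays. Whether doxycycline failed to induce ERα, or was mislabelled within the ERα line, cannot be told apart: the ESR1 probe changed by -0.458 near background, its place in the transcript is not given, and although 31 of 41 classical targets rose with E2 in that line, no array had E2 without doxycycline. A difference between the receptors without added E2 is 1 biological explanation and stays open. It could not be separated from the clone or from the amount of receptor, which the ESR1 probe does not give for ERα. That the receptors had no ligand at all was not measured.

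The ATF4 and amino-acid stress list fell with doxycycline in the ERβ line by camera with its preset correlation, a call lost with an estimated correlation (adjusted p = 0.196). Doxycycline itself is argued against if doxycycline was labelled correctly within the ERα line, as the list had a median of 0.399 there (0.373 to 0.462 without 1 array). As a list call, that rise was lost with an estimated correlation too. With doxycycline the median difference between the lines was -0.00746, but members lay on both sides. GDF15 stood at 10.35 in ERβ cells against 8.23 in ERα cells, and DDIT4 at 13.54 against 14.08. The ERβ cells without doxycycline lay above each other group by a median of 0.812 to 1.277. These medians go with the uninduced ERβ cells standing apart, for example in how they were grown, rather than with a level brought below that of other groups. They do not hold for each member. An effect of ERβ that returns the list to the median level of the other groups stays open.

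The lines without doxycycline differed at 6821 genes. Whether ERβ before induction, whose protein was not measured although the ESR2 transcript was abundant, was the whole cause stays undecided. If more receptor moves a gene further the same way, most genes called both between the lines and with doxycycline in the ERβ line should move in the same direction. With the uninduced ERβ arrays divided so that no array was shared, 61.1% of them moved in opposite directions (57.9% to 63.4% over 6 divisions). Each division left either the line difference or the doxycycline response with a single uninduced ERβ array, whose spread came from other arrays, so this decides nothing. A contribution of ERβ stays open, since on separate arrays 1317 genes had the direction of the E2 response of the ERα line and 602 the opposite one, although for E2 in the ERβ line these were 457 and 727. The share of the 6821 genes with the direction of any of the 3 responses, 24.9%, decides nothing, as the doxycycline response shares the uninduced ERβ arrays with opposite sign. Other differences between the lines as grown cannot be told apart from the receptor with 1 line each: 52% of the genes were called in none of the 3 responses.

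Among 5822 kept probes without exactly 1 gene symbol, which no comparison of the report uses, limma called 506 for E2 in the ERα line, 257 for E2 in the ERβ line, 1 for doxycycline in the ERα line, 378 for doxycycline in the ERβ line, 143 and 172 for the E2 and doxycycline differences, and 1474 between the uninduced lines.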

How the results depend on the processing

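The authors' values with a replicate block and the removal of whole replicate sets were chosen after the data had been seen, as was the numbering of columns by rank match; the other alternatives were planned.

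The order of values below is E2 in the ERα line, E2 in the ERβ line, doxycycline in the ERα line, doxycycline in the ERβ line, the E2 difference and the doxycycline difference. The authors' processed values gave 4683, 3180, 34, 4648, 2495 and 2759 genes, with overlaps of 1707 (E2 in both lines), 21 (both steps, ERα) and 1701 (both steps, ERβ). If these values had been adjusted by replicate, the unblocked fit could understate the spread and raise these counts. Array weights moved E2 in the ERβ line to 3683, doxycycline to 7 and 4177, the differences to 2435 and 2003 and the overlaps to 1690, 3 and 1690. Fitting only the arrays compared gave 1070 genes for E2 in the ERβ line, 0 for doxycycline in the ERα line and 1548 for doxycycline in the ERβ line, with fewer arrays to estimate the spread. A minimum of 2-fold left 746, 391, 615 (ERβ doxycycline), 485 and 605 genes, 1856 between uninduced lines, and overlaps of 210 and 115. Testing every kept probe made the ERα overlap 2. With an estimated correlation 12 gene list calls remained of 45. Where no reason is given, the cause was not tested. No scaling moved the share of rises by over 10 points or the median of all genes by over 0.1.

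With the number of each array as a replicate block, the counts were 3841, 2531, 2, 3784, 1688 and 1969 genes in the order above, and 7833 between uninduced lines. The authors' values with a replicate block gave 1875, 2106 and 1326 for the differences and the ERβ overlap. With the pairing, GREB1 passed on its chosen probe for the E2 difference (-0.59, adjusted p = 0.0108) and ESR1 for E2 in the ERα line (0.58, adjusted p = 0.0244), and the cofactor list for E2 in the ERα line and the NF-kB list for the E2 difference no longer passed. The block changed no other call of a named gene and no other of the 45 list calls. Of the counts, only that of the doxycycline difference moved by over 1.5 times. Lists that had not passed were not compared one by one.

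Leaving out 1 array gave 2346 to 2620, 1389 to 1781, 2 to 3, 2013 to 2536, 941 to 1280 and 1048 to 1327 genes, and 6159 to 6469 between uninduced lines. The overlaps were 775 to 930, 0 to 1 and 583 to 765, the ESR1 change with doxycycline -0.68 to -0.21, that of ESR2 4.60 to 4.76, and the list calls 40 to 48. Leaving out a replicate set, which leaves 2 arrays per group, gave 1458 to 2342, 653 to 1314, 0 to 2, 1017 to 2456, 305 to 682, 411 to 966 and 4693 to 6195 genes and overlaps of 361 to 691, 0 to 0 and 219 to 569, and all but the ERα overlap were lowest without set 1.

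Of the values that changed sign, CCN5 with doxycycline in the ERα line (0.04) became -0.0218 with cyclic loess and -0.0610 with array weights, and -0.11 to 0.21 over the arrays and sets left out, with -0.01 and -0.03 without ERα no-doxycycline arrays 2 and 3, -0.05 without ERα doxycycline array 6 and -0.11 without set 3. GREB1 in the E2 difference (-0.59) was 0.0568 with the mean of its probes. ESR1 in the E2 difference (-0.20) was -0.41 to 0.10, the latter without set 1. Of 448 values of named genes, 25 lost their call with a median shift, 16 with the mean of probes, 14 without the filter on dim probes, 44 with only the arrays compared, 137 at a minimum of 2-fold, at most 4 with other normalizations or variance models, and 110, 68 and 50 without sets 1, 2 and 3, and without 1 array at most 18 (of the 276 values that use ERβ doxycycline array 5). Of the 45 list calls, 2 were lost with a median shift, 1 with cyclic loess, 1 with the authors' values, 4 without the filter on dim probes, 5 with the mean of probes and 5, 5 and 7 without sets 1, 2 and 3, and of the 42 that could be tested on probes detected on all 18 arrays, 6 were. Folds moved by over 1.5 times for 115 without background correction, 106 with the authors' values (with or without the block), 34 with the mean of a gene's probes and 11 with every kept probe, for FGF21 without ERβ doxycycline array 5 (-3.44 and -5.55 for doxycycline in the ERβ line and the difference), and for 1 and 3 values without sets 1 and 2. Signal over background limits what can be seen: dim probes give only bounds, and log2 changes there depend on the background step.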

Other observations

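The hypothesis in this part was written down with its test before the result was seen, although it arose from these data; the pooling of 544 genes was chosen after the results had been seen.

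Several members of lists that did not pass for E2 in either line changed with E2 in both. In the collagen and matrix list the metalloprotease inhibitor TIMP3 rose by 2.52 ± 0.23 in the ERα line and 2.34 ± 0.23 in the ERβ line, and the list had 4 rises and 2 falls in the former and 3 rises in the latter among 29 genes, the same counts as adjusted over the list alone. The fibroblast transcription factor TCF21 rose at least 4.22-fold and 4.66-fold, and the growth factor receptor PDGFRA fell in both lines (-1.64 and -0.58). The ERβ fall of PDGFRA (adjusted p = 0.0134) was lost without ERβ doxycycline array 6 (0.0563) or ERβ E2 array 7 (0.0515) or 8 (0.0588). FKBP4, a cochaperone of steroid receptors, rose by 1.80 and 1.13, and DHCR7, the last enzyme of cholesterol synthesis, by 0.92 and 0.91. FKBP4 is in the heat shock list but also among the classical estrogen targets, which passed. In the p53 list the kinase PLK2 (1.77) and the oxidoreductase TP53I3 (1.27) rose in the ERβ line. In the ERα line 1 of 29 respiratory chain genes rose (0 adjusted over the list alone).

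The 544 genes that E2 raised at least 2-fold in the ERα line rose there by a median of 1.65. In the ERβ line their median change was 0.60 with doxycycline, 0.79 with E2 on top and 1.65 for both steps together. Of them 283 rose with doxycycline in the ERβ line, 342 with E2, 429 with either, and 15 fell with doxycycline. These genes were selected by their ERα change, whose median is therefore raised by the selection.

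A hypothesis for the smaller E2 changes in the ERβ line is that ERβ without added E2 had already raised those genes, which may leave less for E2 to add. If so, genes with a lower E2 response in the ERβ line would have a doxycycline step larger by over 0.5, and if not, by under 0.2. With 1 ERβ doxycycline array left out of the selection and used for the step, the difference of medians was 0.238 on average (0.281, 0.262 and 0.173), which lies between these bounds and leaves the hypothesis undecided.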
